A study of Homo sapiens with 4 samples.

How the data were processed

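Retinal organoids of 4 treatment groups, with 1 library of 5 to 6 pooled organoids per group, were dissociated to single cells and made into 10x Genomics 3' libraries, per the labels' protocols. The deposited files are raw feature-barcode matrices holding UMI counts for 36601 genes and every barcode, before cells were called. Per the submitters' processing notes they were made with bcl2fastq 2.20 and Cell Ranger, with no version given for the latter. The genome build and annotation are not given in the sources used here, so genes are identified by the Ensembl identifiers and symbols of the files and no coordinates are printed. The age of the organoids and the timing of the treatment are not given in the sources used here.

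Cells were called in each library by the OrdMag rule of Cell Ranger: a barcode needed at least 1/10 of the 99th percentile of the UMI counts of the N highest barcodes, with N found by iteration. The resulting minimum was 1272 UMIs in the no RA library, 1073 in RA 1 µM, 740 in RA 10 µM and 1585 in BMS-493. Barcodes with fewer than 500 UMIs, fewer than 500 genes or more than 20% mitochondrial UMIs were removed. Doublets were ranked with Scrublet as implemented in scanpy, and the highest-scoring 0.8% per 1000 barcodes were removed, which took out 438, 492, 461 and 210 barcodes in the same order. Scrublet's own threshold would have marked 151, 213, 1 and 5 barcodes. The kept cells numbered 6964, 7348, 7131 and 4918, held 24784043, 23921180, 16472062 and 24020424 UMIs, and had median mitochondrial shares of 5.62%, 4.22%, 3.50% and 5.30%. Precision was limited by these depths: 3 UMIs in a library correspond to 0.121, 0.125, 0.182 and 0.125 CPM, and a gene with 0 UMIs in a library was given only a lower bound of its fold, computed against 3 UMIs in that library.

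Counts per cell were scaled to 10000 and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were joined to 15 neighbours and clustered with the Leiden method at resolution 1, for all 4 libraries together and without integration, because library and treatment were the same factor. Mitochondrial and ribosomal protein genes and sex-linked genes of the Y chromosome and X inactivation were left out of the clustering and of all named genes, and genes known only by a clone name were left out of the latter. Each of the 34 clusters, counted after splitting, was named from 26 fixed marker lists: at least 3 markers had to be 2-fold above the other cells, their median log2 fold had to reach 0.5, and the cluster's 10 leading genes had to favour no other class. Clusters of fewer than 40 cells were not named, and neither were clusters of low depth without a marker among those 10 genes. A hindbrain or spinal name resting on HOX genes alone was not given, since these are retinoic acid targets. A cluster with strong markers of several classes was split again at resolution 0.3. These details of naming, and the joining of progenitor and Müller glia names into 1 class, were settled after the clusters had been seen. A cluster drawn mostly from 1 library may stand for that library and not for a cell type.

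UMIs were summed over the kept cells of each library, and over each named class with at least 50 cells in both libraries. The 4 comparisons were RA 1 µM, RA 10 µM and BMS-493 each against no RA, and RA 10 µM against RA 1 µM. Ratios of CPM carry exact conditional binomial intervals, levels exact Poisson intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and all covering counting error only. Log2 ratios were computed after adding 5 CPM to both sides. With 1 library per group there were no replicates, so no test, p-value or count of changed genes was computed, and treatment could not be separated from differences in differentiation or handling. Sums over a library mix the makeup of the library with levels per cell, so values within classes stand beside them.

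Gene lists comprised 23 pathway and fate lists besides the marker lists. A member counted as measured with at least 20 UMIs in both libraries together. For each list the median log2 ratio, its percentile among 10000 random lists matched on expression in 50 bins, and the number of members past 1.5-fold in each direction were computed, the last as a rule of size and not a test. For lists with genes at few counts the median was also computed with each count under 3 set to 3 and nothing added. The lists share members: CYP26A1 stands in both the retinoic acid target list and the macula-associated list, and the HOX genes are themselves retinoic acid targets. Named genes were the members of these lists, the 10 highest and 10 lowest log2 ratios per comparison among genes with at least 50 UMIs and 20 CPM in the higher library, and the 5 highest and 5 lowest within each class. Filters, comparisons, lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Single-gene values of a few genes are not reported here. The choice of the retinoic acid target, rod and cone phototransduction lists as the leading ones was made afterwards.

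Shares of cells with a UMI of a gene were computed after thinning each cell to 1000 UMIs, with amacrine-like cells as background. Free RNA was read from barcodes of at most 100 UMIs, and a list was singled out where its lower bound in a treated library exceeded 5 times the upper bound in the no RA library, a multiple chosen after the values had been seen. Alternatives covered a minimum of 2000 UMIs per cell, a mitochondrial limit of 10%, no doublet removal, Leiden resolutions of 0.5 and 2, assignment of each cell by marker score with and without thinning, median-of-ratios scaling, means over cells, subtraction of a free RNA share of 10%, an addition of 1 CPM, and no minimum or a minimum of 200 UMIs for list members. Clustering each library alone, and leaving out clusters with a median mitochondrial share under 0.5%, were added after the data had been seen.

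The ratio and list steps were tested on simulated data: Poisson counts with 200 genes altered per comparison. All genes altered 2-fold or 4-fold came out in the right direction and past 1.5-fold, and 0 unaltered genes passed 1.5-fold. Of genes altered exactly 1.5-fold, however, 13 of 71, 11 of 83, 9 of 62 and 11 of 73 passed 1.5-fold in RA 1 µM, RA 10 µM and BMS-493 against no RA and RA 10 µM against RA 1 µM, so counts of members past 1.5-fold leave out many differences near that size. All 20 genes named by size in each comparison were altered ones. Intervals covered the true ratio for 90.9% to 97.8% of genes by fold and comparison. The simulation has no variation between organoids, so it says nothing of replicate error. Work was done in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.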

Results

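Human retinal organoids grown from H7 A81.BRN3b.mCherry, a reporter derivative of the H7 embryonic stem cell line, were profiled by droplet single-cell RNA sequencing. There were 4 groups with 1 library each: no retinoic acid (no RA), retinoic acid at 1 µM (RA 1 µM), retinoic acid at 10 µM (RA 10 µM), and BMS-493, an inverse agonist of the retinoic acid receptors, at 1 µM. Each library pooled 5 to 6 organoids. The libraries held 39014032 UMIs (no RA), 34779086 (RA 1 µM), 24929080 (RA 10 µM) and 36279885 (BMS-493), and 6964, 7348, 7131 and 4918 cells were kept in the same order. The median depth per kept cell was 2859.5, 2746, 1959 and 4258.5 UMIs, so the RA 10 µM cells were the shallowest and the BMS-493 cells the deepest. No group had a replicate, so no difference could be set against a spread between replicates and none was tested. Levels are CPM, the UMIs of a gene scaled to the total UMIs of the cells summed, which are all kept cells of a library unless a class is named. Brackets hold exact 95% intervals, which cover counting error only.

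The comparison of RA 1 µM with no RA asked how retinoic acid at the lower dose went with cell fate, maturation and regional identity. In the RA 1 µM library 9 of 22 genes that retinoic acid induces were at least 1.5-fold higher and 13 within 1.5-fold, HOXB genes were present where the no RA library had nearly no UMIs of them, and most genes of rod and cone phototransduction were lower. CYP26A1 (ENSG00000095596), the enzyme that degrades retinoic acid, stood at 449.6 CPM against 6.66, a ratio of 67.5 [57.9 to 79.2]. CYP26B1, a second degrading enzyme, had a ratio of 50.3 [36.8 to 70.6], and CRABP2 (ENSG00000143320), which carries retinoic acid into the nucleus, one of 5.34 [5.16 to 5.53]. OPN1SW (ENSG00000128617), the short-wavelength cone opsin, had a ratio of 0.0601 [0.0497 to 0.072].

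Of 22 measured retinoic acid receptor targets and feedback genes, 9 were at least 1.5-fold higher with RA 1 µM and 0 at least 1.5-fold lower, with a median log2 ratio of 0.48 (percentile 100 of 10000 matched random lists). They included DHRS3, which reduces retinaldehyde (73.1 against 11.9), and the transcription factor NR2F1 (402.2 against 223.5). All 6 measured HOX genes were at least 1.5-fold higher, with a median of 1.96, or 6.69 with each count under 3 set to 3. HOXB5 (ENSG00000120075) stood at 38.1 against 0.161, a ratio of 236 [91.9 to 869], and HOXB4, with 0 UMIs in the no RA library, was at least 23.8-fold higher. The other genes with the highest ratios were SERPINA3, TFPI2, the HOXA transcript HOTAIRM1, HOXB2, HOXB6 and HOXB8, with log2 ratios from 2.33 to 3.04. SERPINA3 and TFPI2 led cluster 21.1, named retinal pigment epithelium, with 23 no RA and 62 RA 1 µM cells. The depth of its cells was 3.24 times the library median. A few deep cells may thus carry these 2 ratios, which was not tested.

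Of 17 rod phototransduction genes 12 were at least 1.5-fold lower and 0 higher (median -1.34), and of 14 cone phototransduction genes 11 were lower and 0 higher (median -1.15). GNGT1, the gamma subunit of rod transducin, stood at 106.7 against 724.8, and PDE6H, the inhibitory subunit of the cone phosphodiesterase, at 534 against 1568. The outer segment and cilium list had 13 of 17 members lower (median -1.05), among them IMPG1, a protein of the matrix around photoreceptors, with a ratio of 0.111 [0.101 to 0.121]. The visual cycle list had 5 of 9 lower (median -0.69), the ribbon synapse list 6 of 14 (median -0.56) and the rod fate regulators 4 of 8 (median -0.57), where NRL, the leucine zipper factor of rod fate, stood at 141.5 against 540.1. Photoreceptor precursor markers were lower in 3 of 6 and higher in 0 (median -0.55). Bipolar cell markers were lower in 7 of 12 and higher in 1 (median -1.12) and skeletal muscle markers lower in 5 of 6 (median -1.86), with MYLPF, MYL1 and ACTA1, genes of muscle fibres, at log2 ratios of -3.46, -3.08 and -2.79. With each library clustered alone these 3 genes led a cluster of 89 no RA cells, 1.28% of that library, named skeletal muscle. In the other libraries 0 cells were given that name. TTR (ENSG00000118271), a carrier of thyroid hormone, had a ratio of 0.0708 [0.0662 to 0.0756], and GUCA1C and PCP2 were also among the 10 lowest. TTR led cluster 21.2, named retinal pigment epithelium, with 12 no RA and 0 RA 1 µM cells. The median depth of that cluster was 13204 UMIs, so a few deep cells may carry the TTR ratio, which was not tested. Retinal ganglion cell markers were higher in 6 of 13 (median 0.57), with the neurofilament gene NEFL at 11.5 against 3.67. The ganglion-like cells of all 4 libraries lay in clusters 14.1 and 14.2, whose median mitochondrial shares were 0.446% and 0.315%, against 4.22% over the RA 1 µM library.

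Among regional lists, ventral retina had 2 of 8 members higher and 1 lower (median 0.28), with VAX2, a transcription factor of the ventral eye, at 73.0 against 22.0. Dorsal retina had 2 of 7 lower (median -0.19), nasal retina 1 of 5 higher (median 0.14), temporal retina 0 of 4 past 1.5-fold (median 0.26) and the macula-associated genes 1 of 7 higher (median 0.17), that member being CYP26A1. The remaining lists had medians between -0.16 and 0.26: -0.16 for the Notch pathway, -0.06 for cone subtype and thyroid hormone, 0.02 for dissociation immediate early genes, 0.04 for retinoic acid synthesis, 0.04 for the unfolded protein and integrated stress response, 0.14 for S phase, 0.15 for cholesterol synthesis, 0.18 for glial reactivity, 0.19 for hypoxia and glycolysis, and 0.26 for G2 and M phase. The stress-inducible chaperone gene HSPA6 stood at 79.6 against 13.8.

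Within cells that resembled progenitors or Müller glia, CYP26A1 was at 1141 CPM with RA 1 µM, a ratio of 45.6 [38.8 to 54.0], and the median of the retinoic acid targets was 0.44. Of this class 890 of 1687 no RA cells lay in cluster 11, while 1621 of 2226 RA 1 µM cells lay in cluster 0. CYP26A1 was the first leading gene of cluster 3, also of this class, with 390 no RA and 465 RA 1 µM cells. Within rod-like cells CRABP2 was at 2394 against 103. CRABP2 was among the 10 leading genes of cluster 12, named rod, so the cells were grouped in part by the gene compared. The rod phototransduction median within rod-like cells was -1.61 with clusters of all libraries together and -0.62 with each library clustered alone. It was 0.01 among cells of at least 2000 UMIs, which were clustered and named anew. The rod-named clusters then held 85 and 3 RA 1 µM cells, against 868 and 105 no RA cells. The 0.01 therefore comes from differently named cells and does not show an effect of depth. The joint rod-like cells lay in different clusters, 1203 in cluster 12 and 97 in cluster 13 with RA 1 µM, against 785 and 1050 with no RA. The cone phototransduction median within cone-like cells was -0.57 with joint clusters and -1.30 with each library alone. These medians concern different cells: 50 RA 1 µM and 924 no RA cells were cone-like with joint clusters, and 1039 and 1313 with each library alone.

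**Figure D1:**
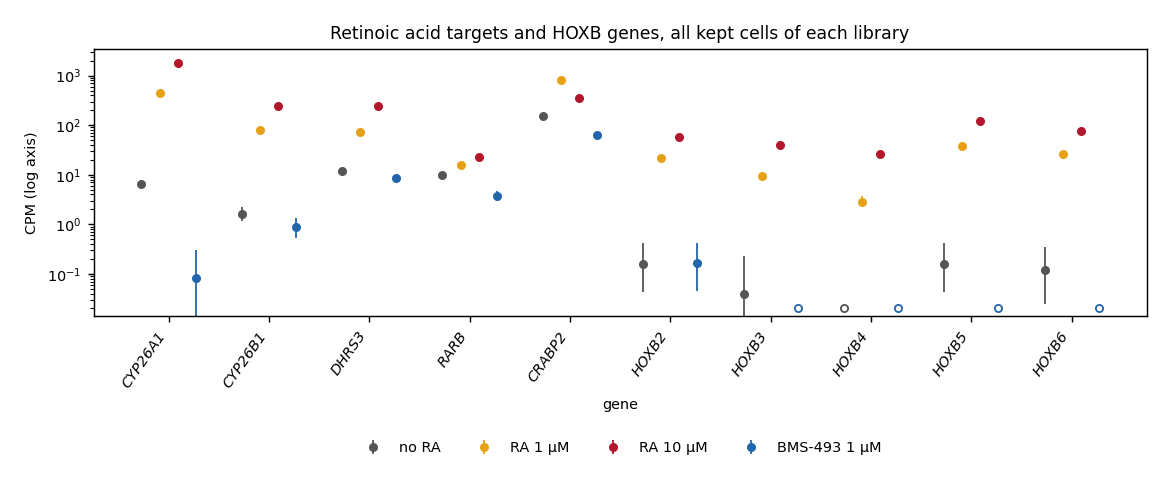
Levels of retinoic acid targets and HOXB genes (CPM, log axis) in all kept cells of each library, 1 point per library. Bars are exact 95% Poisson intervals and open circles at the lower edge mark 0 UMIs. CYP26A1 stands at 6.66 in no RA, 449.6 in RA 1 µM, 1827 in RA 10 µM and 0.083 in BMS-493.

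The comparison of RA 10 µM with no RA asked the same at the higher dose. CYP26A1 stood at 1827 CPM, a ratio of 274 [236 to 322], and DHRS3 (ENSG00000162496) at 238.8, a ratio of 20.1 [17.8 to 22.7]. HOXB5 stood at 120.2 against 0.161, a ratio of 745 [290.4 to 2736]. OPN1SW had 10 UMIs in the RA 10 µM library, a ratio of 0.007 [0.0034 to 0.013].

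Of 22 retinoic acid targets 15 were at least 1.5-fold higher with RA 10 µM and 0 lower (median 0.81, percentile 100), among them CYP26B1 (241.8 against 1.61), the receptor gene RARB (22.8 against 9.85), ZNF703 (33.6 against 4.68) and RARRES1 (14.8 against 1.74). Of 7 HOX genes 6 were higher (median 3.18, or 8.39 at 3 counts). HOXB-AS3, a transcript of the HOXB cluster, was at least 610-fold higher and HOXB9 at least 322-fold. HOXB6, with 3 UMIs in the no RA library, had a ratio of 638 [217.8 to 3098], and HOXB8, also with 3, one of 633 [216.3 to 3076]. HOXB2, HOTAIRM1 and SERPINA3 completed the 10 highest, with log2 ratios from 3.59 to 3.89. SERPINA3 was a leading gene of the deep pigment epithelium cluster 21.1, which held 23 no RA and 42 RA 10 µM cells.

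Rod phototransduction genes were lower in 15 of 17 (median -1.20) and cone phototransduction genes in 12 of 14 (median -1.51, or -2.64 at 3 counts), with 0 members of either list higher. PDE6G, the inhibitory subunit of the rod phosphodiesterase, stood at 6.44 against 87.1, SAG, rod arrestin, at 9.90 against 91.4, and PDE6H (ENSG00000139053) at 233.4 against 1568. OPN1MW had 0 UMIs and was at least 112-fold lower, though reads of this gene and the near-identical OPN1LW cannot be assigned with certainty. Outer segment and cilium genes were lower in 16 of 17 (median -1.42), with RP1, a protein of the outer segment axoneme, at 34.7 against 460.6, and visual cycle genes in 6 of 9 (median -0.94). CRX, the transcription factor of photoreceptor precursors, stood at 206.5 against 240.1 (log2 -0.21) while its partner OTX2 stood at 117.3 against 312.7. The photoreceptor precursor markers, which include both, were lower in 4 of 6 and higher in 0 (median -1.33). Rod fate regulators were lower in 5 of 8 (median -0.80), with NRL at 351.7 against 540.1, and the ribbon synapse list in 6 of 14 (median -0.38). Bipolar cell markers were lower in 8 of 12 and higher in 1 (median -1.38), with CABP5 and PCP2 at log2 ratios of -3.59 and -4.35. Skeletal muscle markers were lower in 4 of 6 (median -1.95) and retinal pigment epithelium markers in 5 of 9 (median -0.81), with TTR at a ratio of 0.0172 [0.0146 to 0.0201]. Cluster 21.2, the deep pigment epithelium cluster that TTR led, held 12 no RA cells and 1 RA 10 µM cell. MYLPF, MYL1 and IMPG1 were also among the 10 lowest, the first 2 being leading genes of the 89 no RA cells named skeletal muscle. Retinal ganglion cell markers went both ways, 5 of 13 higher and 1 lower (median -0.01), the ganglion-like cells being those of low mitochondrial share, and optic stalk markers had 2 of 4 higher (median 0.51), among them VAX2 at 75.2 against 22.0.

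Hypoxia and glycolysis genes were at least 1.5-fold higher in 6 of 17 (median 0.30), with the vascular growth factor VEGFA at 305.9 against 124.2, ADM at 59.1 against 11.9 and the glucose transporter SLC2A1 at 664.4 against 321.8. Cholesterol synthesis genes had 2 of 14 higher (median 0.42), the sterol sensor INSIG1 at 24.5 against 10.6 being 1. Notch pathway genes were lower in 6 of 14 and higher in 1 (median -0.29), with HES5, a Notch effector, at 18.8 against 55.3. Dorsal retina genes went both ways, with 3 of 7 lower and 2 higher (median -0.14), and ventral retina had 3 of 8 higher and 1 lower (median 0.22). The medians of the other lists were -0.23 for cone subtype and thyroid hormone (5 of 13 lower, 2 higher), -0.12 for retinoic acid synthesis, -0.06 for immediate early genes, -0.02 for S phase, 0.00 for macula-associated genes (3 of 7 higher, CYP26A1 among them, and 0 lower), 0.11 for nasal retina, 0.11 for G2 and M phase, 0.17 for temporal retina, 0.31 for the unfolded protein and integrated stress response, and 0.35 for glial reactivity.

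Within progenitor or Müller glia-like cells CYP26A1 was at 4183 CPM, DHRS3 at 383 against 5.54, and the median of the retinoic acid targets was 0.80. These RA 10 µM cells lay mostly in clusters 0 (1034 cells) and 3 (817 cells), the latter led by CYP26A1. Cluster 11 held 1 of them, against 890 of the 1687 no RA cells. Within cone-like cells of each library clustered alone the cone phototransduction median was -1.68, while the joint cone cluster held 924 no RA cells and 1 cell of this library. Within rod-like cells the rod phototransduction median was -0.58 with joint clusters and -2.05 with each library alone. The joint clusters named 112 cells of this library rod-like, 97 in cluster 12 and 15 in cluster 13 against 785 and 1050 with no RA, since 2782 of its cells lay in a cluster that met no naming rule and held CRX at 451 and NRL at 761 CPM.

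**Figure D2:**
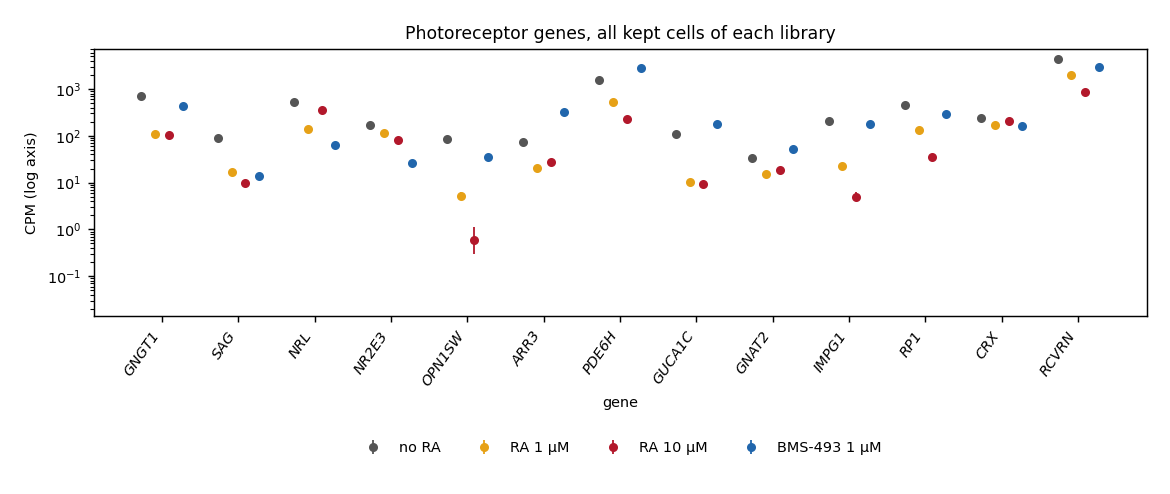
Levels of photoreceptor genes (CPM, log axis) in all kept cells of each library, 1 point per library, with exact 95% Poisson intervals as bars. PDE6H stands at 1568 in no RA, 534 in RA 1 µM, 233.4 in RA 10 µM and 2773 in BMS-493, while NRL is at 64.8 in BMS-493 against 540.1 in no RA.

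The comparison of RA 10 µM with RA 1 µM set the doses side by side. NEUROG1 (ENSG00000181965), a proneural transcription factor, had a ratio of 7.01 [6.27 to 7.86], at 109.9 against 15.7. It led cluster 8, which met no naming rule and held 2782 RA 10 µM and 253 RA 1 µM cells. In that cluster NEUROG1 stood at 241.5 CPM (1613 UMIs) with RA 10 µM and 22.4 with RA 1 µM. The RA 10 µM cells there held CRX at 451 and NRL at 761 CPM. CYP26A1 was 4.06-fold higher [3.98 to 4.15], and HOXB4, HOXB9 and HOXB-AS3 had ratios of 9.22, 6.23 and 7.01. CRABP2 went the other way, at 347.6 against 816.4, a ratio of 0.426 [0.413 to 0.439]. Of 22 retinoic acid targets 7 were at least 1.5-fold higher at 10 µM and 1 lower (median 0.33), and of 7 HOX genes 6 were higher (median 1.42).

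The calcium-binding genes CALB1 and CALB2, with IFITM1, BAALC and STXBP6, were also among the 10 highest, with log2 ratios from 1.87 to 1.97. CALB1 and CALB2 were among the 10 leading genes of cluster 8. Among genes above the UMI and CPM minimum ISOC1 had the lowest log2 ratio, with a ratio of 0.124 [0.113 to 0.137]. The heat shock genes HSPA6 and HSPA1B stood at 16.4 against 79.6 and 74.9 against 257.3, and CABP5, VXN, MCC, RP1, PCP2, GNG13 and DPP10-AS1 had log2 ratios from -2.29 to -1.66. Photoreceptor precursor markers were lower in 5 of 6 (median -0.94) and outer segment genes in 8 of 17 (median -0.56), while rod phototransduction genes were lower in 3 of 17 and higher in 1 (median -0.30), and cone phototransduction genes lower in 3 of 11 (median -0.41). NRL was higher at 10 µM, a ratio of 2.49 [2.38 to 2.59]. Hypoxia genes were higher in 5 of 17 (median 0.15), and retinal ganglion cell markers lower in 5 of 13 (median -0.31, again with low mitochondrial shares in ganglion-like cells), with POU4F1, a transcription factor of ganglion cells, at 0.364 against 3.85.

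The comparison of BMS-493 with no RA asked what went with lower receptor activity. Rod markers were at least 1.5-fold lower in 10 of 11, cone phototransduction genes were higher in 6 of 14 and lower in 1, and retinoic acid targets were lower in 5 of 21 with the other 16 within 1.5-fold. NRL (ENSG00000129535) stood at 64.8 against 540.1, a ratio of 0.12 [0.114 to 0.127], and NR2E3, the nuclear receptor that acts with it, at 25.9 against 169, a ratio of 0.153 [0.141 to 0.167]. ARR3 (ENSG00000120500), cone arrestin, stood at 324.8 against 74.2, a ratio of 4.38 [4.16 to 4.61]. Among genes above the UMI and CPM minimum the lowest log2 ratio was that of TF (ENSG00000091513), transferrin, at 29.5 against 355.1, a ratio of 0.0831 [0.0769 to 0.0897].

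Of 21 retinoic acid targets 5 were at least 1.5-fold lower and 0 higher (median -0.24), with CYP26A1 at 2 UMIs against 165, a ratio of 0.0125 [0.0015 to 0.0459] and CRABP2 at 62.6 against 152.9. HOX genes had too few UMIs in both libraries to be measured. Rod markers were lower in 10 of 11 (median -1.64), with SAG and PDE6G at log2 ratios of -2.36 and -2.35. Rod phototransduction genes, a list with members active in both photoreceptor types, were lower in 9 of 18 and higher in 1, GUCA1B (median -0.59). That median was -0.43 among cells of at least 2000 UMIs. Rod fate regulators were lower in 4 of 8 (median -0.73), and photoreceptor precursor markers in 3 of 6 with 0 higher (median -0.58).

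Cone phototransduction genes were higher in 6 of 14 and lower in 1 (median 0.57, percentile 100), with PDE6H at 2773 against 1568, GUCA1C at 180.1 against 107.3 and the channel subunit CNGB3 at 56.4 against 25.8. Lists with smaller medians also reached that percentile, such as the unfolded protein and integrated stress response (median 0.27, 1 of 14 higher). The lower member was OPN1SW, at 35.6 against 86.3. DMBX1 was among the 10 highest, with a ratio of 4.96 [4.10 to 6.02]. Horizontal cell markers were higher in 4 of 7 (median 0.62), bipolar cell markers higher in 5 of 12 and lower in 1 (median 0.28), with VSX1 at 168.8 against 79.1, and retinal ganglion cell markers higher in 5 of 13 (median 0.48), where ganglion-like cells again had low mitochondrial shares. Retinal pigment epithelium markers were higher in 6 of 10 (median 0.71), with the pigment genes TYRP1 and PMEL at 130.6 against 45.3 and 190.2 against 82.8. These 2 genes were leading genes of cluster 21.2, named retinal pigment epithelium, with 50 BMS-493 and 12 no RA cells. Its median depth was 13204 UMIs, so a few deep cells may carry the difference, which was not tested.

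Glial reactivity genes were higher in 5 of 10 (median 0.63, percentile 100), with the intermediate filament gene VIM at 2941 against 1708 and GFAP, with 3 UMIs in the no RA library, at a ratio of 48.2 [16.1 to 236]. S100A4 and SPARCL1 had the highest ratios by log2, at 145.8 against 19.7 and 35.3 against 1.90. With each library clustered alone SPARCL1 and GFAP led an astrocyte-like cluster of 78 BMS-493 cells, 1.59% of that library, and 0 no RA cells were named astrocyte. The joint clusters named 73 BMS-493 and 33 no RA cells so. Mesenchyme markers were higher in 4 of 7 (median 0.72), with COL1A1, a collagen of connective tissue, at 20.1 against 2.22, and astrocyte markers in 4 of 6 (median 0.68). With each library alone COL1A1 was a leading gene of 341 BMS-493 cells named Müller glia. Neither that clustering nor the joint clusters named a mesenchyme class. At resolution 2 a cluster with 604 BMS-493 and 143 no RA cells was named mesenchyme. ACTA2, IGFBP7, LGALS3 and CRYAB, the last coding for a small heat shock protein, had log2 ratios from 1.58 to 1.80. Skeletal muscle markers were lower in 5 of 6 (median -0.74), and MYL1, MYLPF, TNNC2, RRAD and ISOC1 were among the 10 lowest, with log2 ratios from -2.64 to -2.33. MYL1, MYLPF and TNNC2 were leading genes of the 89 no RA cells named skeletal muscle with each library alone, a name given to 0 BMS-493 cells.

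Macula-associated genes were higher in 3 of 7 and lower in 1 (median 0.34): DIO2, which activates thyroid hormone, stood at 14.5 against 2.02, NPVF at 4.41 against 0.525 and FRZB at 65.2 against 32.8, and the lower member was CYP26A1. Retinoic acid synthesis had 2 of 9 higher and 1 lower (median 0.04), the higher ones being ALDH1A1 (42.3 against 21.2) and ALDH1A3, enzymes that make retinoic acid. Notch pathway genes were lower in 4 of 14 (median -0.23), with HES1 at 105.9 against 218.6. The medians of the other lists were -0.39 for outer segment and cilium (5 of 17 lower, 0 higher), -0.12 for nasal retina, -0.11 for cone subtype and thyroid hormone (3 of 13 higher, 2 lower), -0.08 for ribbon synapse, -0.07 for dorsal retina, -0.05 for ventral retina, -0.05 for S phase, -0.01 for hypoxia and glycolysis, 0.02 for immediate early genes, 0.06 for cholesterol synthesis, 0.17 for G2 and M phase, 0.18 for the visual cycle, 0.24 for temporal retina and 0.27 for the unfolded protein and integrated stress response.

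Within rod-like cells of the BMS-493 library the rod phototransduction median against no RA was 0.25, with 8 of 17 members higher and 1 lower, and 0.30 with each library alone. Of the joint rod-like cells 25 lay in cluster 12 and 247 in cluster 13 with BMS-493, against 785 and 1050 with no RA. Within cone-like cells the cone phototransduction median was 0.34 with joint clusters and 0.82 with each library alone. Within progenitor or Müller glia-like cells TF was at 107 against 1380 CPM and the retinoic acid targets had a median of -0.39. The progenitor or Müller glia-like cells of the no RA and BMS-493 libraries lay mostly in a cluster with 890 and 795 of their cells, and 72 and 1 of the RA 1 µM and RA 10 µM cells.

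**Figure D3:**
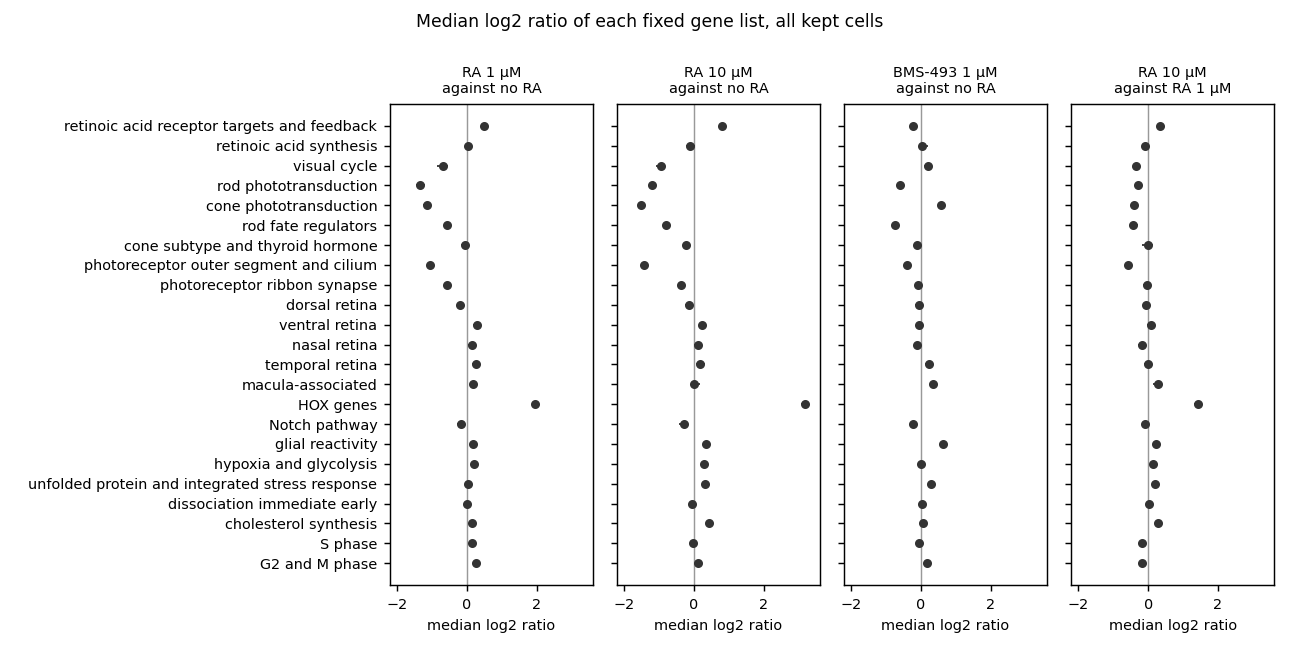
Median log2 ratio of each of the 23 fixed gene lists over all kept cells, 1 panel per comparison, with bars spanning the central 95% of medians after Poisson redraws of the counts. HOX genes, not measured for BMS-493, have no point there. The rod and cone phototransduction lists lie at -1.20 and -1.51 for RA 10 µM against no RA, and at -0.59 and 0.57 for BMS-493 against no RA.

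Shares of cells named as photoreceptors depended on how cells were grouped. Rod-like, cone-like and precursor-like cells together made up 45.6% of the no RA library [44.4 to 46.8], 34.6% of RA 1 µM [33.5 to 35.7], 2.29% of RA 10 µM [1.95 to 2.66] and 32.9% of BMS-493 [31.6 to 34.3] in clusters of all libraries (exact Clopper-Pearson intervals). With each library clustered alone they made up 44.8%, 21.2%, 36.8% and 25.6%. The genes that name these clusters differed between the libraries, so neither set of shares measures a difference in cell numbers.

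With every cell thinned to 1000 UMIs, CRX was seen in 20.2% of no RA cells, 14.1% of RA 1 µM, 16.0% of RA 10 µM and 13.5% of BMS-493 cells, against 1.99%, 0.923%, 1.84% and 3.20% of amacrine-like cells, which should lack it. Cone arrestin ARR3 was seen in 3.46%, 1.31%, 1.90% and 14.3% of cells, and in 0%, 0%, 0% and 3.65% of amacrine-like cells. NRL was seen in 31.5%, 12.4%, 20.7% and 5.82% of cells, and in 5.65%, 0%, 3.67% and 1.37% of amacrine-like cells. The background was higher for RCVRN, a calcium sensor of photoreceptors, seen in 59.1%, 40.5%, 31.4% and 41.5% of cells and in 20.9%, 9.23%, 10.1% and 10.96% of amacrine-like cells. PDE6H was seen in 24.0%, 12.9%, 8.24% and 36.8% of cells and in 7.97%, 2.15%, 0.917% and 16.4% of amacrine-like cells. CYP26A1 was seen in 0.517%, 17.4% and 36.3% of no RA, RA 1 µM and RA 10 µM cells, and in 0 of 4918 BMS-493 cells, which allows a share of cells with a UMI at that depth of up to 0.061% (3 cells of the total) (amacrine-like cells 0%, 2.77%, 6.42% and 0%). The amacrine-like cells numbered 301, 325, 109 and 219, so a count of 0 in them allows up to 0.997%, 0.923%, 2.75% and 1.37%. Without thinning the shares in library order were 41.5%, 29.5%, 26.3% and 33.9% for CRX, 8.52%, 4.15%, 3.88% and 24.7% for ARR3, 46.2%, 22.7%, 29.5% and 10.7% for NRL, and 0.991%, 24.3%, 41.8% and 0.041% for CYP26A1. The median depth of amacrine-like cells was 2053, 1908, 1603.5 and 2534 UMIs, and 431 RA 10 µM cells under 1000 UMIs were left out.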

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

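All tests of explanations in this part were chosen after the results they address had been seen, and the rod markers were taken up for BMS-493 when the value of the rod phototransduction list at 2000 UMIs was already known. The comparison with amacrine-like cells replaced one with free RNA in cells named by the genes tested, which had left free RNA undecided for the rod markers. With 1 library per group, a difference in differentiation or handling between libraries stays open for every pattern below and was not tested, as does the treatment itself.

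Barcodes of at most 100 UMIs, which hold free RNA and entered no comparison, carried transcripts of 2 lists in RA libraries at over 5 times the level in the no RA library. HOX transcripts made up 109.8 CPM there with RA 1 µM (515 UMIs) and 356.5 with RA 10 µM (1625 UMIs), against 0.555 with no RA (2 UMIs), close to the 103.4 and 338.2 in the kept cells of both RA libraries. Macula-associated transcripts, a list that includes CYP26A1, made up 1507 CPM with RA 10 µM (6871 UMIs) against 276.1 with no RA (996 UMIs). Other lists were also higher there, such as retinoic acid targets, at 4412 CPM with RA 1 µM and 5616 with RA 10 µM against 1992, and retinoic acid synthesis, at 1864 and 2214 against 981.2.

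The HOX genes of the RA libraries raise the question of whether their UMIs came from free RNA or from cells of another culture. Levels in progenitor or Müller glia-like cells lay above those in rod-like cells of the same library. The median log2 ratio was 1.99 [1.39 to 2.66] in the library where it was smaller, which argues against evenly spread free RNA as the whole source. With each library clustered alone, that class included clusters of 228 RA 1 µM and 556 RA 10 µM cells with HOXB genes among their 10 leading genes. Such cells may carry the difference. In RA 10 µM, HOXB5 stood at 27 CPM in progenitor cluster 0 against 12.6 in cluster 8, which held CRX and NRL. HOXB2 went the other way, at 4.33 against 14.5. Free RNA thus stays open for progenitor-like cells outside HOXB-led clusters. Cells of a non-retinal culture are argued against for cluster 7, led by HOXB genes, where retinal progenitor markers lay close to those of cluster 0, with a median of -0.38 [-0.52 to -0.23] in the library where it was lower. Cluster 17, also led by HOXB genes, was not covered by that test. A response to retinoic acid may account for the rest and remains a hypothesis.

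The lower cone phototransduction genes with RA 10 µM could come from shallower cells, free RNA in the no RA library or fewer cone-like cells. Among cells of at least 2000 UMIs the list median was -1.43 [-1.54 to -1.34] against -1.51 over all cells, which argues against depth as the whole cause. In the no RA library the list stood higher over all kept cells than in amacrine-like cells, with a median log2 ratio of 2.80 [2.73 to 2.86], which argues against evenly spread free RNA as its main source. Within cone-like cells of each library clustered alone the median was -1.68 [-1.84 to -1.40], but these were different cells, since the joint cone cluster held 924 no RA cells and 1 RA 10 µM cell. Fewer cone-like cells therefore cannot be told apart from a lower level per cell, and either under retinoic acid stays open as a hypothesis.

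The lower rod genes with BMS-493 could come from the deeper cells of that library or from free RNA of rods in the no RA library. Among cells of at least 2000 UMIs the rod markers had a median of -1.37 [-1.48 to -1.31] against -1.64 over all cells, which argues against depth for them. For the rod phototransduction list the same restriction gave -0.43 [-0.46 to -0.41] against -0.59, but that test decides nothing, since the value over all cells already lay at the 1.5-fold bound, and a part played by depth cannot be told apart there. Rod markers over all kept cells of the no RA library stood above amacrine-like cells by a median log2 ratio of 1.97 [1.72 to 2.54], which argues against evenly spread free RNA as the whole cause and leaves a part of it open. Fewer rod-like cells, or cells along another fate, stay open, and the treatment is 1 candidate among these.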

How the results depend on the processing

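Clustering each library alone and leaving out clusters of under 0.5% mitochondrial UMIs were chosen after the data had been seen, and the other alternatives before. No paired analysis was possible because each group had 1 library. Over whole libraries, 16 list medians past 1.5-fold kept their sign under all 9 alternatives and stayed past 1.5-fold in 11 to 16 cases. Of the named genes 174 past 1.5-fold kept their sign under all 8 alternatives, and 164 to 174 stayed past 1.5-fold. Adding 1 CPM in place of 5 could neither turn a sign nor shrink a ratio. Median-of-ratios scaling moved named genes by at most 0.059. These 2 alternatives therefore could hardly fail. Many named genes were also chosen for the size of their ratio in the same counts. Median-of-ratios scaling moved the median of all genes by at most 0.06. With means over cells up to 7 of the 20 genes named by size in a comparison were replaced. Values under an alternative are followed by the reported one in brackets, and except where said the cause was not tested. Depth limits the shallow RA 10 µM library most: a minimum of 2000 UMIs left 3441 of its cells [7131].

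At resolution 0.5, at 2000 UMIs, without doublet removal and by marker score with or without thinning, another class share moved most. The photoreceptor share of cells moved most at resolution 2, at a mitochondrial limit of 10% and with each library alone. In no RA [45.6%] it was 39.7% at a minimum of 2000 UMIs, 34.7% at a mitochondrial limit of 10%, 44.1% without doublet removal, 37.5% at resolution 2 and 42.5% by thinned marker score. In RA 1 µM [34.6%] it was 19.3%, 6.12%, 21.9%, 7.199% and 25.8% under the same alternatives, 28.9% by marker score and 21.2% with each library alone. In RA 10 µM [2.29%] these were 0.552%, 0.639%, 1.23%, 0.799%, 15.6%, 15.6% and 36.8%, and 2.76% at resolution 0.5. In BMS-493 [32.9%] the share was 30.4% at 2000 UMIs, 22.5% at the mitochondrial limit, 30.2% at resolution 2, 28.7% by thinned score, 31.1% by marker score and 25.6% with each library alone. The mitochondrial limit kept 7087 of 7348 RA 1 µM cells, but clusters with 1136 and 942 of them met no naming rule. At resolution 2 clusters with 888 and 867 RA 1 µM cells met none. The falls to 6.12% and 7.199% thus lay mostly in how clusters were named, not in cells lost.

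With at least 200 UMIs per list member, which leaves out weakly measured genes, the retinoic acid target median was 0.78 [0.48] for RA 1 µM and 1.03 [0.81] for RA 10 µM. The same minimum gave rod phototransduction medians of -1.61 [-1.34], -1.68 [-1.20] and -0.76 [-0.59] for RA 1 µM, RA 10 µM and BMS-493, and cone medians of -1.31 [-1.15] and -1.70 [-1.51] for both RA doses. Under the mitochondrial limit the rod medians were -1.18, -1.09 and -0.77, and the cone medians -1.06 for RA 1 µM and 0.47 [0.57] for BMS-493. For RA 10 µM the rod median was also -1.29 with means over cells, -1.28 after free RNA subtraction, -0.91 at 2000 UMIs and -1.08 with no minimum for members, and the cone median -1.27 with means. For BMS-493 the rod median was -0.72 with means, -0.49 after free RNA subtraction and -0.43 at 2000 UMIs, and the cone median 0.71 with means. Between doses the rod median was -0.41 [-0.30] with means, and the cone median [-0.41] was -0.29 with means, -0.28 at 2000 UMIs and -0.29 with no minimum.

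Within classes more values turned, 12 of 320 named genes by marker score and 6 of 240 with each library alone. SST in horizontal-like cells turned for RA 1 µM [-3.04] to 1.86 at the mitochondrial limit and 1.92 at resolution 2, and for RA 10 µM [-2.80] to 1.76 and 1.89. For BMS-493 [-1.26] SST turned to 2.71 and 3.20 there, 0.87 at 2000 UMIs and 0.58 by marker score. By marker score, values in horizontal-like cells turned for OCIAD2 to -0.0175 [1.08] and RCVRN to 0.15 [-1.77] with RA 1 µM, PDE6H to -0.55 [1.78] with BMS-493, and PCP4 to -0.33 [1.71] between doses. In precursor-like cells MT1E turned to -0.0783 [4.90] and MT1F to -0.12 [4.59] with RA 10 µM, and between doses MT1G to -3.49 [2.88] and MT1E to -1.76 [2.36]. In ganglion-like cells HSPA6 turned to -1.45 [4.24] with RA 10 µM and PPP1R27 to -1.15 [1.81] with BMS-493. In rod-like cells SAG turned between doses [1.71] to -1.08 by marker score and -2.70 with each library alone, and GNGT1 to -1.09 [1.98] with the latter. Each library alone also turned APOE to 0.40 [-2.32] and PTGDS to 0.80 [-2.18] in cycling cells of RA 1 µM, PTGDS to 0.98 [-1.88] in those of RA 10 µM, and ISL1 to -2.29 [1.36] in horizontal-like cells of BMS-493. PDC in bipolar-like cells of RA 1 µM turned to -0.15 [1.21] at the mitochondrial limit, and the rod phototransduction median in its rod-like cells to 0.0131 [-1.61] at 2000 UMIs. The clusters named rod at that minimum held 85 and 3 RA 1 µM cells, so the 0.0131 comes from differently named cells. Subtracting free RNA kept the sign of 298 of 320 and turned GNGT1 in precursor-like cells of RA 1 µM to 1.48 [-2.45]. In the rest it left a ratio of 0, as all UMIs of photoreceptor genes, in classes that are mostly not photoreceptors, were subtracted.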

Other observations

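The comparisons named in this part were chosen after the values had been seen, apart from the fixed lists and the rule for named genes. Retinoic acid libraries held 2 clusters led by HOXB genes, cluster 7 with 203 RA 1 µM and 604 RA 10 µM cells and cluster 17 with 114 and 428, with 0 and 1 cells from no RA and 0 from BMS-493. In cluster 7 of the RA 10 µM library HOXB5 stood at 562 CPM against 27 in cluster 0, a progenitor cluster, and CYP26A1 at 6104 against 3082. The eye field gene RAX stood at 163 in both and SFRP2 at 1593 against 1646. In cluster 17 the neuronal gene STMN2 stood at 1159 and HOXB5 at 905. Both clusters came mostly from 1 library and may stand for that library.

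Cone-like cells of the RA 10 µM library, clustered alone, had 12 of 14 cholesterol synthesis genes at least 1.5-fold above those of no RA and 0 below, with a median log2 ratio of 1.10 [0.90 to 1.24]. These were different cells in each library, since the joint cone cluster held 924 no RA cells and 1 RA 10 µM cell. In photoreceptor precursor-like cells the metallothionein gene MT1G, which binds metals, stood at 409 CPM with RA 1 µM, 3042 with RA 10 µM and 169 with BMS-493, against 2.68 with no RA. These cells were cluster 10, whose 10 leading genes included MT1G, MT1F, MT1E and MT1M and 0 precursor markers, so the cells were grouped in part by the gene compared. The RA 10 µM value came from 50 cells. With cells assigned by marker score the log2 ratio of MT1G against no RA was 1.42 in place of 8.63 for RA 10 µM and 0.10 in place of 4.50 for BMS-493, and between doses it turned from 2.88 to -3.49. In rod-like cells of BMS-493, VTN, which codes for vitronectin, stood at 230 against 24.9 and PCP4 at 905 against 132. The rod-like cells came from different clusters: 247 of 272 lay in cluster 13 in BMS-493, against 1050 of 1835 in no RA, where 785 lay in cluster 12. VTN was also among the 10 leading genes of cluster 20, which was named cone.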
